A study of Mus musculus with 3 samples.

How the data were processed

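ChIP-seq was done on intestinal cells of floxed Setd2 mice with antibodies to H3K36me3 and to SETD2, beside an input DNA library, with 1 library each. Per the labels' protocols, sonicated nuclear lysates were used, and the library preparation is not described. The authors deposited 1 peak list per antibody. Per the names of the deposited files and peaks, each list was called on 1 ChIP library against the input, by a program that names its peaks MACS, so replicates could not be compared. The submitters' processing notes name CASAVA 1.8 and the human build hg19. The aligner, the caller's version and the filters are not given in the sources used here.

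Each line of the deposited lists holds a chromosome, a start and end in base pairs, a peak name and a score. The score is the authors' own value for a peak. Its scale is not stated, and its minimum near 30 in both lists points to a fixed calling threshold. It was used only to rank and filter peaks within a list, never as an amount. The lists hold no read numbers, so depth, counting error and the level of the input at a peak are unknown. A narrow-peak caller splits or misses a mark that is spread thinly over gene bodies, so a gene without a peak is not shown to lack the mark.

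The human build named in the notes cannot be that of the coordinates. Against chromosome lengths entered from memory, as no file of them was at hand, and for the other builds only for chromosomes 2, X and Y, 7 peaks of both lists lay past a chromosome end in hg19 (X and Y), 6 in the mouse build GRCm37 and 3 in GRCm39, and 0 lay past any end in GRCm38. Coordinates are therefore given as GRCm38, counted from 1. Moving all H3K36me3 peaks by 10 kb in either direction lowered the share in protein-coding genes from 56.5% to 52.8% and 52.2%, moving them by 100 kb to 47.5% and 48.9%, and by 1000 kb to 42.5% and 41.9%. SETD2 peaks moved by the same distances showed no such fall (33.3% unmoved, 32.3 to 39.8% moved). Gene spans came from a RefSeq table of the GRCm38.p6 assembly with 49993 positioned genes. After removal of 340 genes whose positions lie on patch scaffolds (starts below 3 Mb on chromosomes other than Y) and of genes outside the chromosomes, 49599 remained, of which 21775 are protein-coding. The table has no strand, exons or sequence.

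The share of peaks in genes used peak midpoints, and peaks were shuffled 1000 times on their own chromosome with widths kept, between the outermost gene or peak of that chromosome. Assembly gaps and poorly mappable sequence could not be left out of the shuffles. Observed numbers were compared with shuffled ones by a two-sided permutation p, 2 times the smaller tail with 1 added to the count. Overlap of the lists needed 1 bp. The 18 gene lists were fixed before the data were examined and hold 2434 entries, of which 2431 were found by symbol or synonym. A gene counted when a peak touched its span by 1 bp, and each list was compared with 10000 random lists matched on gene length in 20 bins, with Benjamini-Hochberg adjustment over the 18 lists of each ChIP. Shares have exact Clopper-Pearson 95% intervals, which treat peaks as independent.

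Genes were named by a rule fixed before the data were examined: the 12 genes with the highest-scoring peak of each ChIP, up to 12 genes with both kinds of peak, up to 4 members of each list by score, Setd2 and Dvl2, and the 5 highest peaks of each ChIP outside protein-coding genes. Not every gene or peak that the rule selects is printed. Alternatives were a stricter score, other overlap distances, all annotated genes, any overlap in place of midpoints, merged peaks, autosomes alone, wider gene bodies and lists not matched on length. Left out were planned comparisons that need strand, exons or sequence: promoters, exons, position along the gene, repeats and GC content. The distance to either gene end was added in place of promoters.

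The procedures were tested on simulated peaks. With 20% of peaks planted in genes, the H3K36me3 comparison was called in 100 of 100 simulations and the SETD2 comparison in 94. With nothing planted they were called in 7 and 3. With 4 planted overlaps the overlap was called in 100 simulations, and with 0 planted in 0. Shuffled peaks never gave more than 3 overlaps, so 4 planted ones could hardly fail to be called. In these simulations of genes and overlaps, peaks that were not planted were placed by the same shuffle as the reference. They therefore do not check for errors from clustered peaks, assembly gaps or poor mappability. For the H3K36me3 list test, 30 genes hit 5 times as often as their lengths give were called in 88 of 100 simulations. A list of 400 genes hit 2 times as often was called in 97. These simulated calls were not adjusted over the fixed lists, so the power of the adjusted test may be lower. The simulated lists were drawn from all protein-coding genes. Power may also be lower for lists of short genes, which have fewer expected hits. In the real data, 3 of 28 housekeeping genes held an H3K36me3 peak against 0.584 expected. That list had permutation p = 0.039 but adjusted p = 0.23, and was not called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.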

Results

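Chromatin from intestinal cells of 6-week-old C57BL/6 mice with a floxed Setd2 allele pair was profiled by ChIP followed by sequencing. SETD2 is the histone methyltransferase that places trimethylation on lysine 36 of histone H3 (H3K36me3), a mark found over the bodies of transcribed genes. One ChIP used an antibody to H3K36me3, another an antibody to SETD2, and an input DNA library without antibody served as the control for both. Each of the 3 libraries was a single sample, the labels name no Cre driver, and no library lacking SETD2 was analysed here. The values that follow therefore describe where the 2 peak lists lie, and the p-values compare peaks with shuffled positions, genes with random genes, or the peaks of the lists with each other, not conditions or animals. The question that the design poses is where the mark and its enzyme sit in these cells, and whether they sit at the same places.

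The H3K36me3 list held 1806 peaks that together covered 1130.0 kb, and the SETD2 list held 186 peaks over 156.6 kb. H3K36me3 peaks had a median width of 602 bp (interquartile range 526 to 676 bp), and 7 of them were wider than 2 kb. SETD2 peaks had a median width of 732 bp (572 to 920 bp). The caller's score ran from 30 to 82.0 in the H3K36me3 list and from 30.01 to 1717 in the SETD2 list, where 19 peaks passed a score of 100. No H3K36me3 peak did. In the H3K36me3 list 1459 peaks (80.8%) shared their exact score with another peak, and 15 peaks of 351 to 400 bp all scored 42.6. The numbers of reads behind the peaks are not given in the lists, so the depth is unknown and no counting error can be attached to a score.

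H3K36me3 peaks lay in gene bodies more often than random positions did. The midpoints of 1021 of the 1806 peaks (56.5%, 95% exact binomial interval 54.2 to 58.8) fell within a protein-coding gene, against 40.6% of shuffled peaks (95% of shuffles between 38.3 and 42.7). This was 1.39 times the shuffled share (permutation of positions, two-sided p = 0.0020, the smallest that 1000 shuffles can give). Peaks moved by 100 kb in either direction still stood at 47.5% and 48.9%, so part of the excess does not depend on the exact peak positions. Whether moved peaks stayed in the same gene or reached other genes nearby was not tested. Of all peaks, 106 (5.87%, 4.83 to 7.05) had their midpoint within 1 kb of either end of a protein-coding gene, 1.89 times the shuffled 3.11% (permutation p = 0.0020). Start and end of a gene could not be told apart, because the gene table used gives no strand, and exons, introns and UTRs were not assigned.

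In all, 983 protein-coding genes (4.51% of 21775) were touched by an H3K36me3 peak, against a mean of 691 genes for shuffled peaks (637 to 750 over 100 shuffles; permutation p = 0.020, the smallest they can give). The marked genes had a median span of 63.9 kb. This was above the 17.2 kb of all protein-coding genes and below the 118 kb of the genes that shuffled peaks touched (101 to 137 kb; permutation p = 0.020). A total of 66 genes held more than 1 peak, led by Cog5, which encodes a Golgi complex subunit, with 4. The highest-scoring H3K36me3 peak covered Mt1, the gene of the metal-binding protein metallothionein 1 (chromosome 8, 94179253 to 94180512, GRCm38, score 82.0). It was followed by peaks in Trip4 (chromosome 9, 65874474 to 65875069, score 73.7), Tmem267 (score 73.2), the integrin gene Itgad (score 67.1) and Tdrd1 (score 61.3). Next came 1 peak shared by the overlapping zinc finger genes Zfp981 and Zfp993 (score 60.7) and the peaks of Zmynd8, a chromatin reader (59.9), Mterf3 (57.3) and Fut8, a fucosyltransferase (56.9). The widest peak of the list, 9557 bp, crossed Hjurp, the chaperone of the centromeric histone, and its neighbour Mroh2a (chromosome 1, 88260770 to 88270326, score 58.3). Of the 772 peaks that touched no protein-coding gene, 119 touched a long non-coding RNA gene, 20 a pseudogene and 631 no annotated gene. The highest of these lay in the non-coding gene 3632454L22Rik (chromosome X, 135053435 to 135054754, score 69.5) and 2.34 kb from Tmem267 (chromosome 13, 119612803 to 119617708, 4906 bp, score 61.0). Others among the highest lay near Gm5923 (chromosome X, 32147905 to 32149299, score 59.8) and near Vmn2r111 (chromosome 17, 22577046 to 22577727, score 58.7).

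SETD2 peaks showed no such preference for genes. Midpoints of 62 of the 186 peaks (33.3%, exact interval 26.6 to 40.6) lay in a protein-coding gene, against 39.2% of shuffled peaks (32.8 to 46.2; permutation p = 0.11). Within 1 kb of a gene end lay 5 peaks (2.69%, 0.878 to 6.16), against a shuffled 2.92% (permutation p = 1). The share of peaks in genes was 23.2 percentage points lower than in the H3K36me3 list (95% interval of the difference 16.1 to 30.4; permutation of the labels among peaks, drawn 100000 times, p = 1e-05, the smallest they can give). Only 2 of the 10 highest-scoring SETD2 peaks touched a protein-coding gene, and 0 of the 10 overlapped an H3K36me3 peak. The top peak, with a score of 1717, lay 15.1 kb from Adgre5, the gene of the leukocyte receptor CD97 (chromosome 8, 83756434 to 83757420). The next lay at 170757859 to 170758657 on chromosome X (score 1067; nearest protein-coding gene Asmt, 79.8 kb away) and at 93576760 to 93577600 on chromosome 12 (score 719; nearest protein-coding gene 682 kb away). Others lay 69.0 kb from Creb3l1 (chromosome 2, 92093177 to 92094159, score 673) and 32.5 kb from Gng4 (chromosome 13, 13860410 to 13861380, score 609).

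**Figure D1:**
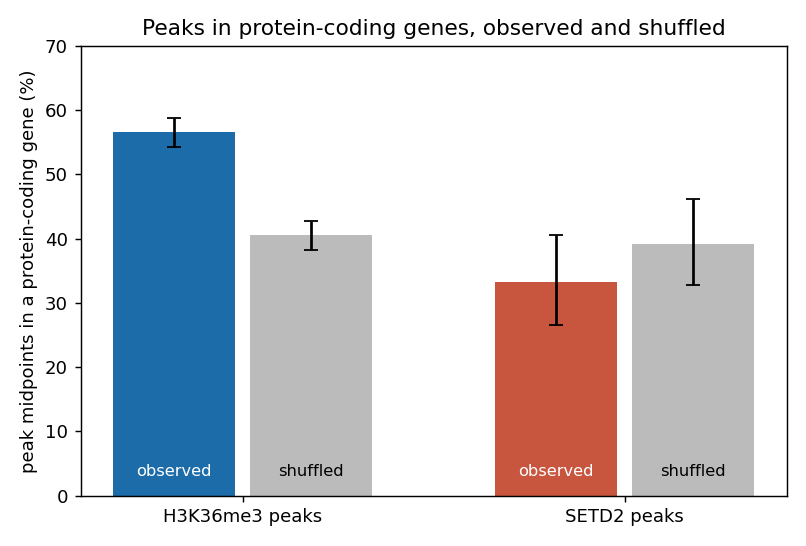
Share of peak midpoints that fell within a protein-coding gene (percent, y axis) for the H3K36me3 and SETD2 lists, as observed (coloured bars, 95% exact binomial interval) and after shuffling on the same chromosomes (grey bars, the middle 95% of 1000 shuffles). H3K36me3 peaks stood at 56.5% against 40.6%, and SETD2 peaks at 33.3% against 39.2%.

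SETD2 peaks touched 64 protein-coding genes, against a mean of 74.8 for shuffled peaks (57 to 99; permutation p = 0.16). The highest-scoring of them lay in Lama1, a laminin chain of basement membranes (chromosome 17, 67741123 to 67741925, score 441), and Flt1, a receptor for vascular endothelial growth factor (chromosome 5, 147610992 to 147611849, score 421). Peaks in Ppp1r9a (score 289), Dop1b (score 233), the ciliary transport gene Ttc21b (score 222) and the urea transporter gene Slc14a2 (score 111) followed. Lower in the list stood Pxylp1 (score 93.8), Wdr76 (85.7), Abhd6 (77.4), the collagen gene Col4a6 (75.8), the phosphodiesterase gene Pde7b (63.1) and the potassium channel gene Kcnh1 (59.5). Each of these genes held 1 SETD2 peak, and of these 12 genes Flt1 also held an H3K36me3 peak. Of the 124 SETD2 peaks outside protein-coding genes, 18 touched a long non-coding RNA gene, 4 a pseudogene and 102 no annotated gene.

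Called peaks of the mark and of its enzyme overlapped at few positions. An H3K36me3 peak overlapped 7 of the 186 SETD2 peaks by at least 1 bp (3.76%, exact interval 1.53 to 7.60), where shuffled SETD2 peaks gave a mean of 0.181 overlaps and never more than 3 (permutation p = 0.0020, the smallest possible). The shuffles place peaks independently, also in assembly gaps, so this p-value does not allow for clustered peaks and may overstate the evidence. On chromosome 4, 1 pair shared 1292 bp in the predicted gene Gm42346 (SETD2 peak 145446196 to 145447706, score 45.5; H3K36me3 score 43.3). Another on chromosome 4 lay in the overlapping zinc finger genes Zfp978 and Zfp991 (147141153 to 147142214, score 31.4; H3K36me3 score 37.0). On chromosome 8, 1 pair lay at the pseudogene Gm20946 near the defensin gene Defb33 (20832925 to 20835382, score 53.1; H3K36me3 score 47.9) and 1 at 19966480 to 19967768 (score 38.04; H3K36me3 score 35.98). A pair on chromosome 16 (3325196 to 3326364, score 35.1) was 266 kb from the olfactory receptor gene Olfr161. The last pairs were on chromosome 18, at 14102870 to 14103737 (score 30.2; H3K36me3 score 58.7), 130 kb from Zfp521, and in the non-coding gene G630055G22Rik (48009953 to 48011015, score 161; H3K36me3 score 31.8). Regions with 10 or more pseudogenes within 500 kb, a measure chosen after the overlaps were seen, held 5 of the 7 pairs, and regions with 5 or more predicted genes within 500 kb held 1. Without the pseudogene regions 2 overlaps were left against a shuffled mean of 0.153 (permutation p = 0.022), and without the predicted-gene regions 6 against 0.182 (permutation p = 0.0020). Both lists were called against the same input, and part of the excess may come from that shared control, which was not analysed here.

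Counted by gene, 13 protein-coding genes held both kinds of peak, against 7.19 for length-matched gene sets (95% of 10000 sets 3 to 12; permutation p = 0.047) and 2.89 if the lists were independent of each other and of gene length. They included Flt1, whose H3K36me3 peak (chromosome 5, 147725106 to 147725680, score 39.1) did not overlap its SETD2 peak, and Lrp1b, a lipoprotein receptor family member (SETD2 score 38.9, H3K36me3 score 32.9). Others were the polycomb group gene Phc3 (SETD2 score 36.05, H3K36me3 score 32.7), the sarcoglycan gene Sgcd (33.6 and 36.4), D5Ertd579e (33.0 and 31.2) and the DNA repair gene Fancc (31.87 and 31.98). Erc1, outside the 12 genes that the naming rule gives, was the remaining gene away from duplicated families. The other 6, Gm42346, Gm2808, Zfp993, Rex2, Zfp978 and Zfp991, were left out with the regions of many pseudogenes, and 7 genes against 5.72 expected then remained (permutation p = 0.68). All of these 6 but Gm2808 lie close together on chromosome 4, and Zfp978 and Zfp991 were touched by the same overlapping peaks. The matched gene sets take genes as hit independently, so the p-value for all peaks may overstate the evidence. With 5 kb added at either side of each gene, 14 genes held both against 8.25 (permutation p = 0.058). With peaks at or above the median score, which left 29 genes with a SETD2 peak, 3 genes held both against 1.76 (permutation p = 0.51); the ratio to expectation was 1.70, against 1.81 for all peaks.

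Setd2 itself carried 2 H3K36me3 peaks, the higher at 110548013 to 110548721 on chromosome 9 (score 35.0), and no SETD2 peak. Dvl2, a Dishevelled protein of the Wnt pathway, carried neither. The list of 24 writers and readers of H3K36 methylation also included demethylases, such as Kdm2a and Kdm4a, and other related genes. Of these 24 genes, 3 held an H3K36me3 peak against 1.58 expected for their lengths: Setd2, Psip1, a reader of the mark (score 33.5), and Nsd2, an H3K36 methyltransferase (score 32.2). None of the 24 held a SETD2 peak, with 0.120 expected. Among 32 Wnt pathway genes, 4 held an H3K36me3 peak (2.04 expected), among them Znrf3, a ubiquitin ligase that removes Wnt receptors (score 38.9), Csnk1a1 (34.7) and the β-catenin gene Ctnnb1 (34.5). The Wnt pathway list had 1 SETD2 peak, in the transcription factor gene Tcf7l1 (chromosome 6, 72685668 to 72686432, score 31.6).

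No excess over gene length was detected among genes of the intestinal epithelium. Of 30 absorptive enterocyte genes 1 held an H3K36me3 peak (1.55 expected): Sis, the brush border sucrase-isomaltase (chromosome 3, 72910705 to 72911038, score 56.1). Of 24 crypt stem and progenitor genes 3 did (1.55 expected), namely the proliferation marker Mki67 (score 40.5), Znrf3 and Cd44 (31.6). The 15 goblet cell, 13 Paneth cell and 18 enteroendocrine and tuft genes held 0, with 0.487, 0.122 and 0.602 expected. With so few expected hits, a depletion could not have been detected in these lists, and a modest excess could have been missed. Markers of other cells in the tissue gave 0 of 22 immune genes (0.613 expected) and 0 of 18 smooth muscle, fibroblast and endothelial genes (0.944 expected).

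Splicing factors, housekeeping genes and zinc finger genes had the lowest p-values in the H3K36me3 list, and no list passed correction over the 18 lists. Of 36 splicing factors 5 held a peak (1.44 expected; permutation p = 0.029, adjusted p = 0.23), among them the spliceosome helicase gene Snrnp200 (score 37.6), the epithelial splicing regulator Esrp1 (35.5), Qk (32.5) and Srsf3 (31.5). Of 28 housekeeping genes 3 did (0.584 expected; permutation p = 0.039, adjusted p = 0.23), among them Eef2, a translation elongation factor (score 40.5), and Rack1 (39.8). Of 424 zinc finger genes 27 did (16.5 expected; permutation p = 0.016, adjusted p = 0.23), with Zfp981 and Zfp993 (60.7), Zfp385b (48.9) and Zfp36, which encodes an RNA-binding protein (46.4), the highest. Without regions of many pseudogenes the zinc finger count was 14 against 14.9 expected. That setting dropped peaks but kept all 424 genes in the list. Zinc finger genes in such regions could then not be hit, so the fall from 27 was partly fixed by that choice. Ribosomal protein genes had 3 of 81 with a peak (0.832 expected): Rplp2, Rpl9 and Rps13, all with scores near 35. Proteasome genes had 3 of 40 (1.15 expected), namely Psma3, Psmb4 and Psmd1, and respiratory chain genes 2 of 96 (1.85 expected), namely Ndufb3 and Atp5j2. Without length matching, the ribosomal protein and respiratory chain counts lay below expectation (3.66 and 4.36 expected). Splicing factors (1.64 expected), housekeeping (1.27) and proteasome genes (1.82) still lay above it. At the other end, 4 of 1461 olfactory and vomeronasal receptor genes held a peak (8.89 expected; permutation p = 0.094, adjusted p = 0.38): Vmn2r18, Olfr490, Vmn2r1 and Vmn2r30. Homeobox cluster genes had 0 of 39 (0.589 expected), and genes specific to other tissues 1 of 30 (1.05 expected), the synaptic gene Syt1 with a score of 30.04.

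In the SETD2 list zinc finger genes were the list that passed correction. SETD2 peaks touched 6 of the 424 (0.945 expected; permutation p = 0.00040, adjusted p = 0.0072): Zfp978, Zfp979, Zfp982, Zfp984, Zfp991 and Zfp993. The list did not pass without length matching (6 against 1.26; permutation, adjusted p = 0.065) or with peaks at or above the median score (3 against 0.37; permutation, adjusted p = 0.18). All of them belong to 1 array of related zinc finger genes and pseudogenes on chromosome 4, in which Zfp978 and Zfp991 share a peak, and reads there may not be assignable to a copy. The random lists draw genes from the whole genome as if each were hit independently, so the p-value does not allow for hits that cluster in 1 array and overstates the evidence. Between 145 and 148 Mb, an interval picked by eye after the peaks were seen, lay 9 SETD2 peaks and 9 H3K36me3 peaks. The interval is a run of SETD2 peaks less than 1.5 Mb apart, a gap set to return it, and gaps of 1 Mb or less gave 146 to 148 Mb with 6 peaks of each ChIP. No test is given, since the peaks themselves set the interval. Leaving out regions of many pseudogenes removes the whole array, so the 0 zinc finger genes that then held a SETD2 peak were fixed by that choice. Apart from the zinc finger and Wnt lists, the SETD2 peaks touched 0 genes of the 16 other lists, and at most 0.332 were expected in any of them.

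**Figure D2:**
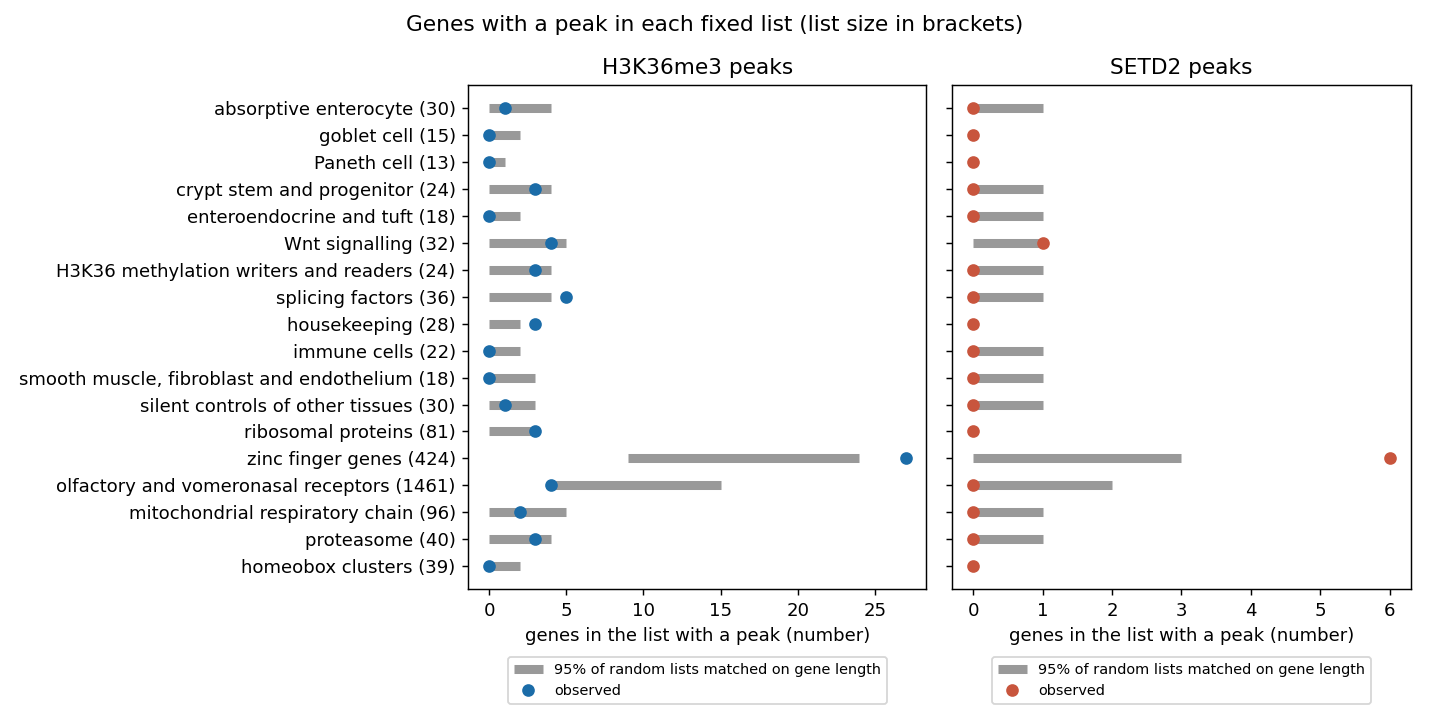
Number of genes with an H3K36me3 peak (left) or a SETD2 peak (right) in each of the 18 fixed lists, with the number of genes found in brackets; dots are observed numbers and grey bars span the middle 95% of random lists matched on gene length. Zinc finger genes lay above the bar in both panels, with 27 and 6 genes, and splicing factors and housekeeping genes in the left panel, with 5 and 3.

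**Figure D3:**
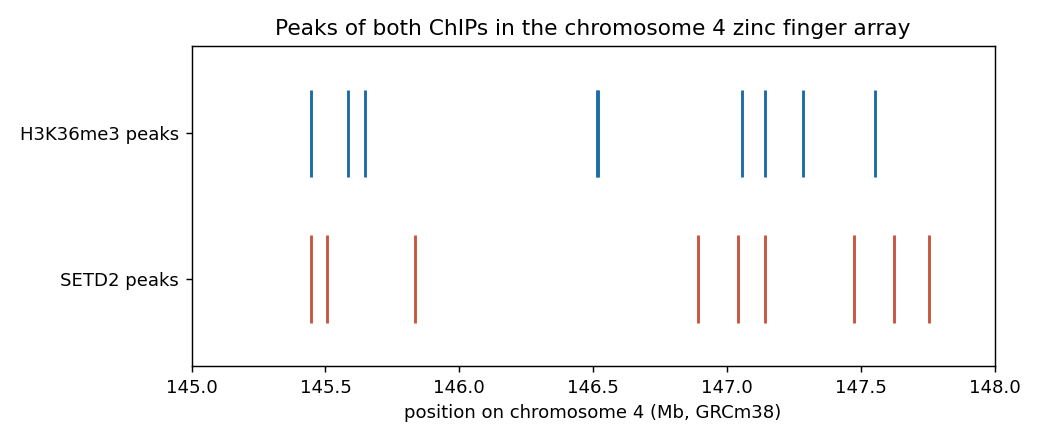
Positions of the 9 H3K36me3 peaks and the 9 SETD2 peaks between 145 and 148 Mb of chromosome 4 (x axis, Mb, GRCm38), each peak drawn as a vertical line at its start. The peaks of both ChIPs coincide at Gm42346 and at Zfp978 and Zfp991.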

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

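All tests in this part were chosen after the results were seen, except that of whether overlapping peaks lie in genes. The share of peaks in protein-coding genes was 23.2 percentage points higher in the H3K36me3 list than in the SETD2 list, and a permutation of the antibody labels among peaks gave p = 1e-05. Noise confined to low-scoring SETD2 calls does not account for this. The 62 highest-scoring SETD2 peaks had 29.0% in genes (exact interval 18.2 to 41.9), with an upper bound below the 54.2% lower bound of the H3K36me3 list. The 62 peaks of middle score and the 62 of lowest score each had 35.5% (23.7 to 48.7), so these groups could not be told apart. The interval of the highest-scoring peaks also holds the shuffled 39.2%, so noise among SETD2 peaks of any score is not ruled out. Arrays by the pseudogene measure held only 32 of the 186 SETD2 peaks, and without them 32.5% lay in genes (25.2 to 40.5). Leaving out so few could not have raised the share to that of the H3K36me3 list. Arrays by this measure are therefore too few to account for the difference. What stays open is that sequence absent from the assembly, repeats or a weak antibody may give SETD2 peaks outside genes, or that SETD2 binds there in these cells. A library lacking SETD2 would be needed to tell these apart and was not analysed here.

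A pattern for a closer look is where the 7 SETD2 peaks that overlap an H3K36me3 peak lie. Regions with 10 or more pseudogenes within 500 kb held 5 of the 7 and 27 of the other 179 SETD2 peaks (15.1%), 1 of the 5 exactly at that limit, and regions with 5 or more predicted genes held 1 of the 7. The pseudogene measure was chosen with these overlaps in view, so reads from unassembled copies, as gene and pseudogene arrays for the overlaps inside them could give, stay open. Without the pseudogene regions 2 overlaps were left, both on chromosome 18, against a shuffled mean of 0.153 (permutation p = 0.022). These 2 had 3 and 2 pseudogenes within 500 kb, so regions past the limit do not hold every overlap. The limit was set with the overlaps in view, and the shuffles still ran over the regions left out. This result therefore cannot exclude reads from arrays or other copies as the whole source. Of the 7 peaks 2 had their midpoint in a protein-coding gene (exact interval 3.67 to 71.0%), too few to tell whether SETD2 leaves its mark at transcribed genes there. Repeats without pseudogenes, and the shared input, remain untested for the 2 on chromosome 18.

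The excess of zinc finger genes in the SETD2 list may come from reads from 1 gene and pseudogene array on chromosome 4, where all 6 genes lie, or from true enrichment there, and these cannot be told apart. The test of the list also took its genes as independent, which neighbours in an array are not. Without regions of many pseudogenes the number of such genes was 0, but this removes the whole array and so fixes the outcome. H3K36me3 is known to cover zinc finger gene clusters, and copy number in this region was not tested for lack of reads.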

How the results depend on the processing

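The alternatives named for pseudogenes, predicted genes, gene ends and pooled lists were chosen after seeing the data. The share of H3K36me3 peaks in genes stayed above the shuffled share, and that of SETD2 peaks stayed below it without passing the threshold, under all annotated genes, any overlap, a score at or above the median, merged peaks, autosomes and both regional exclusions. The overlap of the lists passed its threshold under every alternative run; its number was 5 with at least 50% of the SETD2 peak covered, 3 for peaks at or above the median score, 10 within 10 kb and 2 without regions of many pseudogenes. Genes with both peaks stood at 1.81 times their expectation, and lost their call with 5 kb added at either side (14 genes, 1.70 times, permutation p = 0.058), at or above the median score (3 genes, 1.70 times) and without regions of many pseudogenes (7 genes, 1.22 times). Lists past correction in the SETD2 data numbered 0 without length matching (zinc finger genes 6 against 1.26), 0 at or above the median score (3 against 0.37) and 0 without regions of many pseudogenes (0 against 0.738, which that choice fixes), against 1. Zinc finger genes passed with 5 kb added (7 genes) and without regions of many predicted genes (6 genes), each with permutation, adjusted p = 0.0036. Leaving out the predicted-gene regions removed none of the 6 genes, and the 5 kb setting only added Zfp990 to them. Neither setting therefore tests whether the zinc finger excess goes beyond the array on chromosome 4. In the H3K36me3 data the number was 1 without length matching, olfactory and vomeronasal receptors (4 genes, 65.9 expected, permutation, adjusted p = 0.0036), which are short. Median widths were 616 bp (H3K36me3) and 836 bp (SETD2) at or above the median score. The cause of the other changes was not tested. No window of 100 kb held over 5% of a list (at most 3 and 2 peaks), so leaving out pile-ups would have removed nothing. Promoters, exons, position along the gene, gene bodies without their first 1 kb, and repeat and GC content were not run for lack of strand, exons and sequence. No paired analysis was possible because each group holds 1 library. Read depth behind each peak is unknown.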

Other observations

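Some of the fixed lists were pooled after they were seen to lean up or down in the H3K36me3 data, so the pooled counts describe that leaning and do not test it. Housekeeping, ribosomal protein, proteasome, splicing factor and respiratory chain genes together had 16 of 280 with a peak, such as Eef2, Rack1, Rplp2, Psmb4 and Ndufb3, against 5.79 expected from their lengths and 12.7 without length matching. Olfactory and vomeronasal receptor, homeobox, immune, stromal and other tissue-restricted genes had 5 of 1570 against 12.03 expected, and 70.9 without length matching. The pooled epithelial lists had 4 of 99, Sis, Mki67, Znrf3 and Cd44, against 4.28. Gene density around these genes was not examined.

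Pseudogene-rich regions held 17.2% of SETD2 peaks (12.1 to 23.4) against 6.44% of shuffled peaks (permutation p = 0.0020). For H3K36me3 peaks the shares were 8.86% (7.59 to 10.3) against 6.30% (permutation p = 0.0020). The pseudogene measure was chosen after the overlaps of the SETD2 peaks were seen. Shuffles also place peaks independently, which does not allow for clustered peaks, so these p-values may overstate the evidence. Chromosome X held 14 of the 186 SETD2 peaks (7.53%) and 56 of the 1806 H3K36me3 peaks (3.10%). No expected share for this chromosome was computed, so neither list is shown to favour or avoid it.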
